A study of Homo sapiens with 10 samples.

How the data were processed

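Total RNA from the human lung adenocarcinoma cell line NCI-H441 was measured on 10 Illumina HumanWG-6 bead arrays, 5 from cells given vehicle (DMSO, 0.1%) and 5 from cells given the compound CLEFMA at 1 µM, each for 12 h. Groups and replicate numbers were taken from the sample titles. The labels differ on how many cultures stand behind the arrays: the series text names 5 per group, the treatment protocol 4 wells per group and the extraction protocol 3 biological replicates. Nothing states that each array is an independent culture, so the p-values measure only the spread between these samples, which may be technical.

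The authors' deposited value table holds log10 values for 48803 probes. Its base and its background subtraction were inferred from the values, since the software, background method and normalization are not given in the sources used here. Against log10 of the mean scanner signal, probe means followed a slope of 1.01 between 3 and 4 and of 1.04 between 2 and 3, and bent to 1.38 between 1 and 2. This is the shape of a signal after subtraction of a background of about 69.9 scanner units, with 5.92 scanner units per unit of the table. On each array 24.2% to 25.2% of probes sat at that array's lowest value. The other deposited table, of scanner signal intensity, has 10 columns whose names match no sample. They were therefore used only as 1 mean per probe over all 10, to settle the scale.

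The deposited log10 values were turned back to linear units, an offset of 3 units (17.8 scanner units) was added, and log2 of the sum was quantile normalized between arrays over all probes. Log2 differences are on this scale, which understates the change of dim genes. The plan, made before the data were examined, was a normexp background correction from negative controls or detection p-values with a filter on detection p. Because the table used here has neither and is already background subtracted, no further correction was made, and the fallback filter fixed in the plan was applied. It kept 44606 probes whose mean log2 value exceeded the 25th percentile of all values (1.59). Of these probes, 19267 were above background, taken throughout as a log10 value above 0.2, on fewer than 5 arrays.

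Probes were named from the platform annotation, with symbols updated through Entrez gene identifiers. It gave 27578 probes 1 gene symbol, 27541 of them matched by identifier, and 13 probes several symbols; 21212 probes were not listed and are unnamed here. Each gene was represented by its probe with the highest mean, which left 17752 genes. Probes without a single symbol were tested only at the probe level.

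Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate, all 10 arrays), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Where a gene was above background on no array of a group, the fold is a lower bound. It sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest value above background and the probe's own value. Camera tested 23 gene lists fixed before the data were examined, with a preset correlation of 0.01, and was repeated with an estimated correlation; fry was the other set test. The lists cover NRF2 targets, glutathione, heat shock, amino acid and integrated stress response, the unfolded protein response, metallothioneins, p53 targets, the G1/S and G2/M phases, cholesterol synthesis, NF-kappaB, interferon, hypoxia, autophagy, the BCL2 family, immediate early genes, proteasome, oxidative phosphorylation, aryl hydrocarbon receptor targets, lung epithelial markers, epithelial-mesenchymal transition, and markers of fibroblasts and leukocytes.

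Genes were named by a rule fixed in advance. It takes the 10 largest rises and 10 largest falls among passing genes whose groups did not overlap, 10 stress genes whatever their result (HMOX1, NQO1, GCLM, TXNRD1, SLC7A11, HSPA1A, DDIT3, ATF3, CDKN1A and SQSTM1), and up to 3 passing members of each list. The rule gave 27 genes, all of them measured; other genes named in the text were chosen after their values were seen. The test of genes was tried on simulated data with the real means and spread of 17752 genes. It recovered 29.9% of genes changed by 0.5 on the log2 scale, 82.1% of those changed by 1 and 100% of those changed by 2, with 5 false calls among 146. The simulated noise was independent between genes and had no array standing apart, so these shares may not hold for the real arrays.

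Alternatives covered the offset, the normalization, the deposited values without further processing, the filter, the probe rule, the variance model, array weights, replicate number as a block, and each array left out in turn. Those added after the data were seen included stand-ins for the planned background settings and another filter on dim probes. They also left out arrays that stood apart or fitted replicate number 5 as a batch. Figures were drawn with matplotlib.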

Results

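Gene expression was measured in NCI-H441 cells, an established human lung adenocarcinoma line, 12 h after addition of 1 µM CLEFMA (5 arrays, treated) or of the DMSO vehicle alone (5 arrays, control). CLEFMA is a small molecule that the series title ties to oxidative stress and necrotic death of these cells. Each array reported 48803 probes, of which 49.1% to 53.8% were above background. Pairwise correlations between arrays over the probes kept by the filter ranged from 0.973 to 0.993. Control 3 had the lowest mean correlation with the other arrays, 0.978, against 0.986 to 0.990 for the others. The number of arrays limits the precision of every value below.

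The comparison of treated with control cells asked which transcripts differed after 12 h of the compound. Of 27 measured targets of NRF2, the transcription factor of the oxidant and electrophile response, 15 rose in the treated cells. Among them were the aldo-keto reductases AKR1C2 (16.7-fold), AKR1B10 (15.7-fold) and AKR1C3 (11.6-fold), enzymes that reduce carbonyl compounds. Their log2 differences were 4.06 ± 0.15, 3.97 ± 0.26 and 3.54 ± 0.17 (SE, n = 5 per group). The order and size of these folds depend on the processing and on the probes used. Across the alternatives the log2 differences of AKR1B10 ran from 2.66 to 5.28, against 3.26 to 3.60 for AKR1C3, with 1 tested probe each. Those of AKR1C2 ran from 1.10 to 4.84, where 1.10 was the mean over its 4 probes, of which only the brightest changed. SLC7A11, the light chain of the cystine-glutamate exchanger, rose 3.75-fold. Few genes fell. The prostaglandin transporter gene SLCO2A1 fell by 0.94 ± 0.14 on the log2 scale, the most among the 4 that were above background in both groups.

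In limma 47 of the 17752 genes tested were higher and 6 were lower in treated cells, and in all 53 the values of the groups did not overlap. Over all genes, 444 (2.5%) had groups that did not overlap, against 0.794% by chance. Of the genes that passed, 24 were higher by at least 2-fold as fitted and 0 were lower by as much, where 3 were lower by as much at an unadjusted p under 0.05. At that unadjusted level 795 genes were higher and 795 lower.

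**Figure D1:**
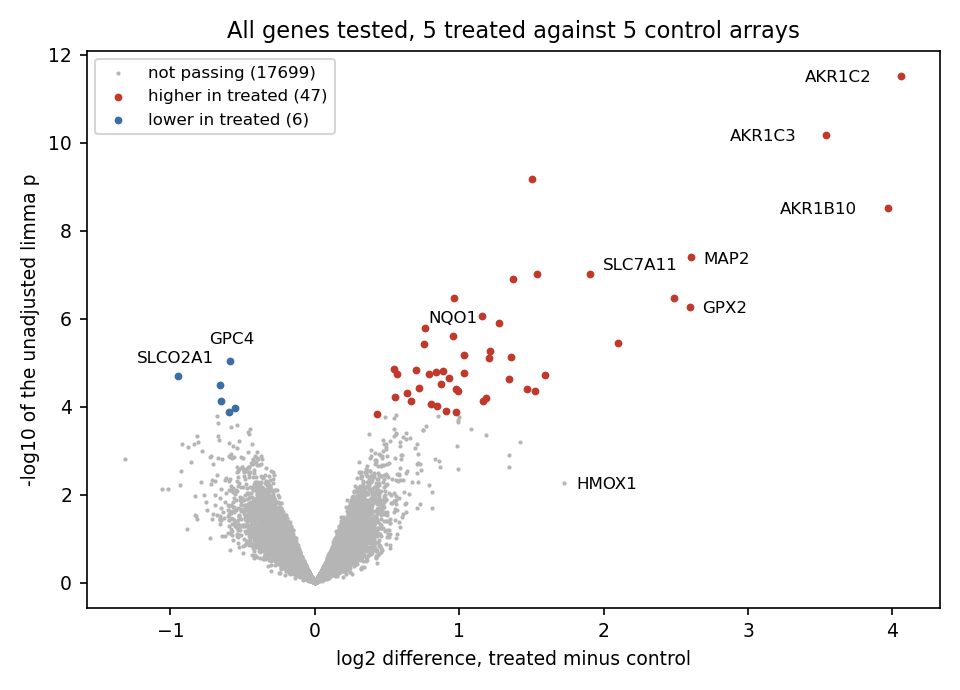
Log2 difference of each gene (treated minus control, 5 arrays per group) against −log10 of its unadjusted limma p. The 47 genes higher in treated cells reach 4.06 on the log2 axis, while the 6 lower genes all lie within 1 unit of 0; HMOX1, at 1.72, did not pass.

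The 10 largest fitted rises went beyond these reductases. The microtubule-associated protein gene MAP2 rose 6.09-fold (log2 difference 2.61 ± 0.21, limma adjusted p = 1.43e-04), and GPX2, a glutathione peroxidase of epithelial cells, rose 6.05-fold (2.60 ± 0.27). AKR1B15 rose 5.61-fold, KIAA0319 3.02-fold and AFP, the gene of alpha-fetoprotein, 2.91-fold. Limma adjusted p-values of these 10 genes ran from 5.42e-08 for AKR1C2 to 0.0111 for KIAA0319. CYP4F3, a cytochrome P450 that hydroxylates leukotrienes, rose from near background, being above it on 1 of 5 control arrays. Its log2 difference of 2.10 ± 0.26 depends on the offset and floor, with a range of 1.01 to 6.73 across the alternatives. It did not pass with the background added back (1.01, limma adjusted p = 0.078) or on the deposited values (6.73, limma adjusted p = 0.649). AKR1B15 was above background on 3 of 5 control arrays, with a range of 1.38 to 3.88. Log2 differences of MAP2 ran from 1.48, the mean over its 4 probes, to 3.00 across the alternatives, and those of GPX2 from 1.58 to 3.63. Those of AFP ran from 0.86 to 2.15 and those of KIAA0319 from 0.84 to 2.51. KIAA0319 did not pass in 10 of 27 alternatives. Probes of one gene did not always move together. For AKR1C2 the brightest of 4 probes changed, while the other 3 differed by 0.05 to 0.14. A second MAP2 probe differed by 2.59 and the remaining MAP2 probes by 0.44 and 0.27, and a second CYP4F3 probe differed by 0.14. Reductase family members are close in sequence, so the values of AKR1C2, AKR1C3, AKR1B10 and AKR1B15 are uncertain as to which member was bound.

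Targets of NRF2 were the list with the largest mean shift. Of the 27 members measured, 15 rose, 0 fell and 12 did not pass; adjusted over the list alone, 26 were higher. The count of 15 was 8 under median scaling and 10 on the deposited values, and at most 20, with array weights. The difference was positive for all 27, with a mean of 1.31 and a median of 0.99 (camera adjusted p = 6.73e-54; adjusted p = 0.0123 with an estimated correlation). NQO1, a quinone reductase, rose 2.42-fold (log2 difference 1.28 ± 0.14, limma adjusted p = 0.00173). TXNRD1, thioredoxin reductase, rose 1.87-fold (0.91 ± 0.16, limma adjusted p = 0.0453), and the ferritin light chain gene FTL 1.46-fold. HMOX1, heme oxygenase, had the widest spread among the named genes. Its mean differed by 1.72 ± 0.51, with every treated array above every control array, but it did not pass (limma adjusted p = 0.337). Without treated 5 it differed by 1.12 and passed (limma adjusted p = 0.0143). The mean difference of the NRF2 list was 1.20 over the arrays numbered 1 to 4 and 1.75 between the arrays numbered 5.

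**Figure D2:**
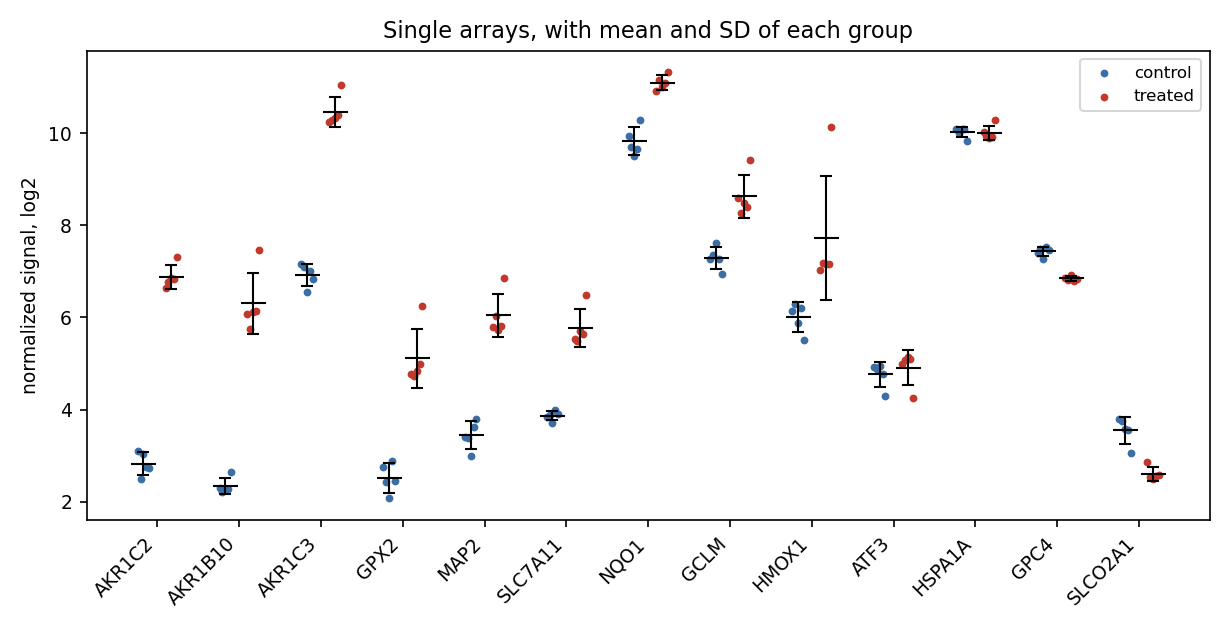
Normalized log2 signal of 13 genes on each array (5 control and 5 treated, placed by replicate number), with group mean and SD. The treated arrays lie above all control arrays for AKR1C2 through HMOX1, with treated 5 the highest for HMOX1 at 10.14, while ATF3 and HSPA1A overlap and GPC4 and SLCO2A1 lie lower.

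Of 29 measured genes of glutathione synthesis and use, 5 rose, 0 fell and 24 did not pass; 8 were higher adjusted over the list alone. The mean difference was 0.41 (camera adjusted p = 4.58e-10; adjusted p = 0.0403 with an estimated correlation). The genes that rose were GPX2, SLC7A11 (log2 difference 1.91 ± 0.17), both subunits of glutamate-cysteine ligase, GCLC (1.47 ± 0.23, limma adjusted p = 0.0189) and GCLM (1.34 ± 0.20, limma adjusted p = 0.0126), and glutathione reductase, GSR (1.16 ± 0.13). All 5 are also in the NRF2 list. None of the other 24 passed in limma, where 6 were higher and 0 lower at an unadjusted p under 0.05, and as a set they had a mean of 0.14 (camera unadjusted p = 1.84e-04; 0.0194 with an estimated correlation). Without treated 5 the mean of the whole list was 0.35. In this list, GSTP1 differed by 0.30 ± 0.12 and GSS, glutathione synthetase, by 0.08 ± 0.10.

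The list of amino acid and integrated stress response genes had a mean difference of 0.21 (camera adjusted p = 1.26e-05; adjusted p = 0.135 with an estimated correlation). Of its 35 members 2 rose, over all genes and adjusted over the list alone. They were SLC7A11 and its partner chain SLC3A2 (0.67 ± 0.11, limma adjusted p = 0.0292), which carry amino acids across the membrane. The 34 members outside the NRF2 list had a mean of 0.16 (camera unadjusted p = 3.12e-05; 0.0542 with an estimated correlation), and without control 3 the mean of all 35 was also 0.16. Under median scaling the mean of all 35 was 0.09 and on the deposited values 0.145, and camera passed in each. The stress transcription factors in this list did not pass: ATF3 differed by 0.15 ± 0.18 and DDIT3 by 0.09 ± 0.15, and ATF4 by 0.13 ± 0.10.

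Proteasome subunits shifted together by a small amount. All 27 measured had positive differences, with a median of 0.35 and a range of 0.05 to 0.58 (camera adjusted p = 4.51e-15; adjusted p = 0.114 with an estimated correlation). No subunit passed over all genes in limma, where 19 were higher at an unadjusted p under 0.05; 18 were higher adjusted over the list alone. Relative to the mean of all arrays, the list was at 0.40 on treated 5, against 0.07 to 0.16 on the other treated arrays, and at −0.29 on control 3, against −0.15 to −0.09 on the other controls. The mean difference of 0.32 was 0.26 without treated 5, 0.29 without control 3 and 0.24 without control 3 and both arrays numbered 5, and camera passed in each. Across all alternatives the lowest mean was 0.19. PSMB5, a catalytic subunit, differed by 0.48 ± 0.11, and PSMD11, of the regulatory particle, by 0.51 ± 0.14.

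As many as 4 lists also passed in 45 other splits of the arrays among 100 tried. No other split gave any of these 4 lists as small a camera p. The 4 were picked because they passed in the real split, so this ranking favours it. The other 19 of the 23 lists did not pass camera. In the autophagy and lysosome list (adjusted p = 0.396) 1 of 32 genes rose, the cargo receptor SQSTM1, by 2.24-fold (log2 difference 1.16 ± 0.20, limma adjusted p = 0.0292). That list passed in fry (adjusted p = 0.0352). The G1/S and DNA replication genes had a mean difference of 0.12 (adjusted p = 0.0542) and the lung epithelial markers one of −0.11 (adjusted p = 0.0602). Neither had a member that passed, and both means changed sign across the alternatives, but G1/S passed in 13 of 30 alternatives and the lung markers in 11 of 30, fry included. Among these, G1/S passed with number 5 as a batch (camera adjusted p = 0.00395) and without control 5 (mean 0.22, 1.79e-06), treated 2 (0.0236) or treated 4 (0.0315); the lung markers passed without control 3 (0.0483) or treated 2 (0.031). With an estimated correlation the adjusted p was 0.817 for G1/S and 0.135 for the lung markers, and the G1/S mean was 0.06 without control 3 and 0.06 without treated 5. Of the lung markers, AQP4, a water channel, differed by −1.31 ± 0.32 (limma adjusted p = 0.196), and fry, which does not compare the list with other genes, gave an adjusted p of 6.84e-04. The 10 fibroblast markers and 14 leukocyte markers measured had means of −0.02 and 0.05. No gene passed in the lists of heat shock, unfolded protein response, metallothionein, p53, G2/M, cholesterol, NF-kappaB, interferon, hypoxia, BCL2 family, immediate early, oxidative phosphorylation, aryl hydrocarbon receptor and epithelial-mesenchymal genes. These 14 lists had means between −0.15 and 0.06 and camera adjusted p-values between 0.158 and 0.979. Across 30 alternatives the metallothioneins passed in 5, oxidative phosphorylation in 3, and the unfolded protein response and G2/M in 2 each; with an estimated correlation their adjusted p-values were 0.527, 0.762, 0.762 and 0.866. Of their 308 genes, limma gave 14 higher and 11 lower at an unadjusted p under 0.05. The immediate early list held 5 of the lower genes and 0 higher, and adjusted over the list alone 2 of its 30 genes were lower, EGR1 (−0.84 ± 0.19) and FOS (−0.60 ± 0.13). Adjusted over the list alone, 1 gene was higher in the p53 list and 1 in the hypoxia list, 3 were higher in the autophagy list and 1 was lower among the lung markers. Median, mean and test differed in sign for the heat shock, interferon, aryl hydrocarbon receptor and fibroblast lists. The heat shock gene HSPA1A differed by −0.01 ± 0.10 and CDKN1A, a p53 target, by 0.05 ± 0.20. Across the alternatives the differences of HSPA1A, CDKN1A and DDIT3 took either sign.

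**Figure D3:**
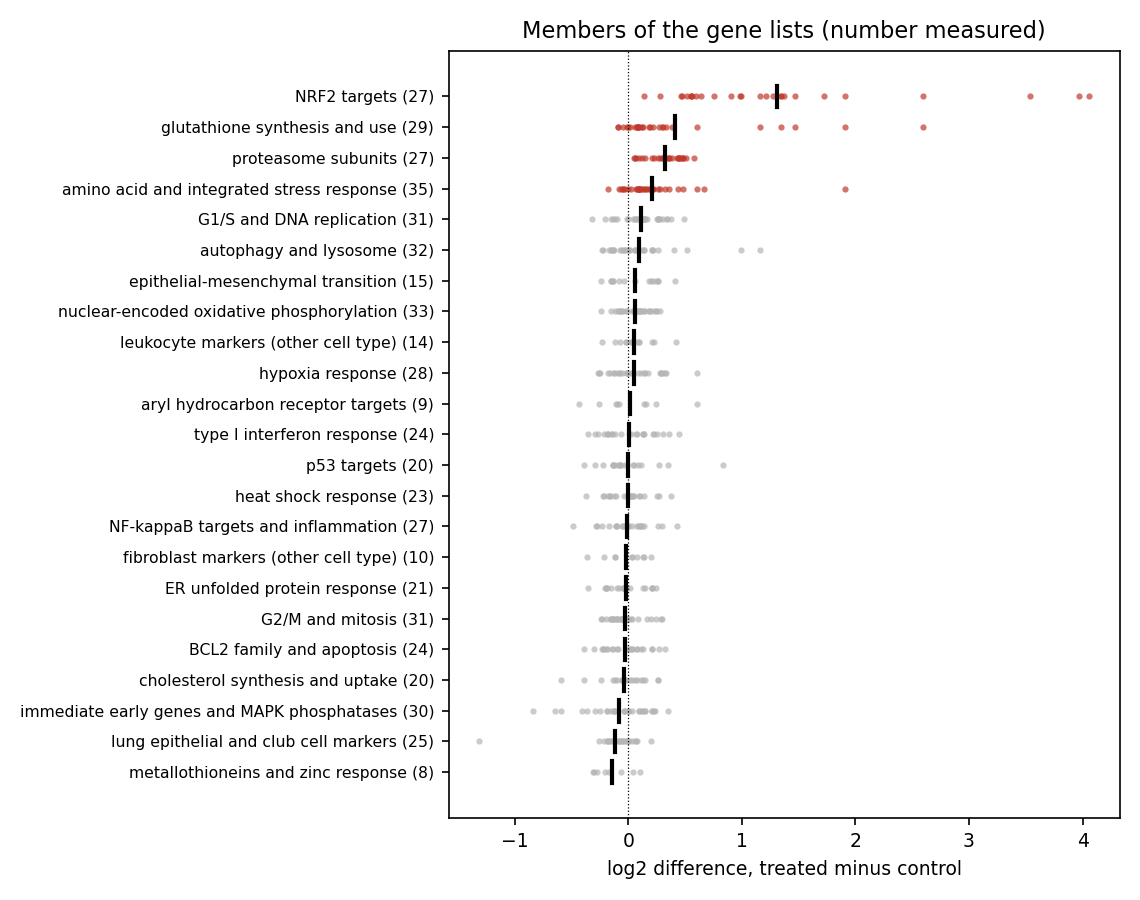
Log2 difference (treated minus control) of each measured member of the 23 gene lists, as points, with the list mean as a bar; lists that passed camera are in red. The NRF2 list reaches from 0.14 to 4.06, and the proteasome subunits lie together between 0.05 and 0.58.

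All 6 genes that fell are named here. Besides SLCO2A1 (limma adjusted p = 0.0114), RNF215 fell by 0.66 ± 0.10 on the log2 scale, ALDH1A3, a retinaldehyde dehydrogenase, fell by 0.65 ± 0.11, and GPC4, a heparan sulfate proteoglycan of the cell surface, fell by 0.59 ± 0.08 (limma adjusted p = 0.00745). REDIC1 and SRPX were above background on 4 and 3 of the control arrays and on 0 treated arrays, so they have only bounds: REDIC1 was at least 1.09-fold lower (limma adjusted p = 0.0394) and SRPX at least 1.00-fold lower (limma adjusted p = 0.0463). A second REDIC1 probe differed by 0.09. The size of these falls also depends on the processing: SLCO2A1 ranged from −1.46 to −0.46 and RNF215 from −1.02 to −0.32 across the alternatives, so a 2-fold fall is not excluded. The fitted values of REDIC1 ran from −4.81 to −0.17 and those of SRPX from −12.99 to −0.18; both lower ends came from the deposited values, where neither passed, and neither gene can be ranked against the others.

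With 1 array left out, the number of higher genes fell to 28, 26 and 29 without controls 1, 2 and 4, and to 30, 26 and 28 without treated 1, 3 and 4; the number of lower genes was between 1 and 3 without any of these or without treated 2. Of the 22 named genes that passed, 11 passed whichever array was left out, and those that did not were KIAA0319, GCLC, GCLM, SQSTM1, TXNRD1, SLC3A2, SLCO2A1, RNF215, ALDH1A3, REDIC1 and SRPX, whose limma adjusted p reached at most 0.162, for TXNRD1 without treated 5.

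**Figure D4:**
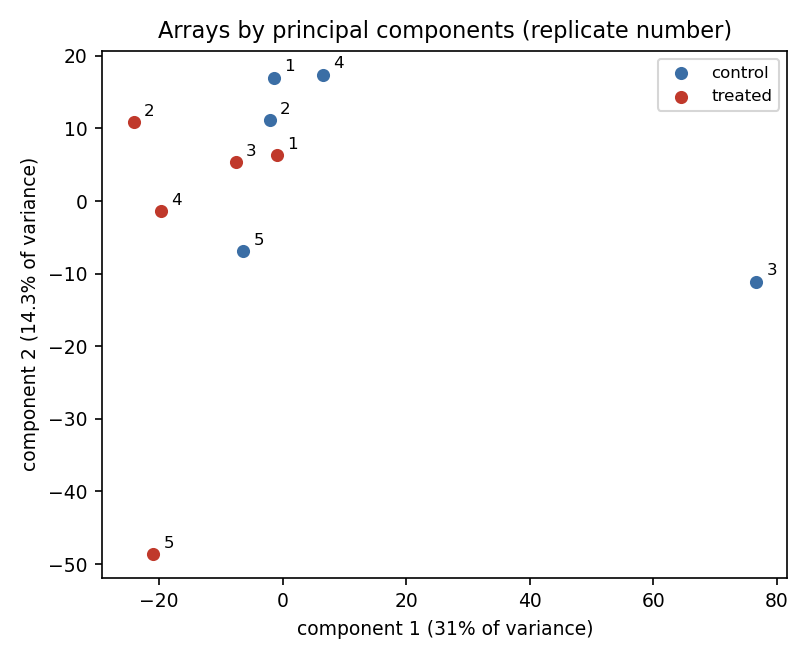
Principal components of the 10 arrays over all probes kept, numbered by replicate, with the percent of variance on each axis (component 1, 31%; component 2, 14.3%). Control 3 stands apart on component 1 at 76.6 and treated 5 on component 2 at −48.6.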

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

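The tests of explanations in this part were chosen after the results were seen. A value stood out where an array's gap to its nearest neighbour, divided by the range of its group, exceeded Dixon's 95% critical value of 0.71 for 5 arrays. This held for 23 of 66 sets of 5 values (34.8%), 15 of them for treated 5 and 3 for control 3. Chance would give 5% if the sets were independent. They are not, since several are NRF2 targets or means that contain them, so 1 high array is counted many times. On treated 5 the values were high for 13 sets, most of them of NRF2 targets. Log2 levels there were 7.46 for AKR1B10, 11.05 for AKR1C3, 6.24 for GPX2, 6.49 for SLC7A11, 10.14 for HMOX1, 9.15 for GCLC, 9.42 for GCLM and 10.99 for TXNRD1. Outside that list, AKR1B15 was at 5.76, MAP2 at 6.85 and CYP4F3 at 5.13 on the same array, and the means of the NRF2 list and of the proteasome subunits were 8.63 and 9.23.

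The rise of NRF2 targets in treated cells was set against 3 technical explanations, and the tables argue against each as its whole cause. Without the aldo-keto reductases, whose probes may bind each other's transcripts, the median difference of the remaining 24 genes was 0.94, all 24 were positive and 12 passed. Without control 3, 14 members were higher, against 15 with it. Without the quantile normalization made here the mean difference was 1.32, against 1.31 with it. Any normalization already in the deposited values could not be tested. Means of the list were higher on every treated array than on any control, and the labels name no other difference between the groups. A response to the compound is a hypothesis. The list was fixed before the data were examined, but these tests of explanations were chosen after the results were seen. Nothing states that each array is an independent culture. Whether slides or shared cultures also differed between the groups was not tested. The mean difference was 1.20 over the arrays numbered 1 to 4 and 1.75 at number 5. A test of number 5 against numbers 1 to 4 was run once. Its result is not reported, because array 5 was singled out from these same values.

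Control 3 had a mean correlation of 0.978 with the other arrays, and 656 of its genes lay more than 1 log2 unit from the other controls (308 higher, 348 lower), against 13 to 74 genes on the other controls. It was not a treated array under a wrong label, as far as its NRF2 targets show: their mean was 6.72, against 6.76 to 6.88 on the other controls and 7.94 to 8.63 on the treated arrays. The mean of 24 fibroblast and leukocyte markers, 11 of them above background on all controls, was 2.92, within the other controls' 2.92 to 3.09, which argues against a broad excess of such cells. Single markers went both ways, so a smaller share of such cells is not excluded. LYZ was at 2.95 against 4.36 to 4.75. Of the 24 markers, 6 were highest on control 3, near an even share between 5 controls. Among these 6 were the brightest, CD68 at 8.90 against at most 8.41 and LUM at 7.72 against at most 7.51. CD3D and COL1A2, also among them, were above background on 0 controls. Of all 24, 0 lay more than 1 log2 unit above the mean of the other controls. Noise of single probes may be part of what sets control 3 apart. The deviations of 5424 probe pairs of the same gene had a correlation of 0.265 there. On the other controls it was 0.145 to 0.394, or 0.118 to 0.386 with control 3 left out of their reference. Such noise was not the only cause, since the covariance was 0.0564 on control 3, against at most 0.029 on the others by the latter reference. What the probes share on control 3 stays open.

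The arrays numbered 5 shared a deviation across the groups. Of 74 genes over 1 log2 unit off on control 5, 86.5% deviated the same way on treated 5, against 40% to 75% for the other numbers. Those other shares rest on 15, 36, 656 and 13 genes for numbers 1 to 4, and number 5 was singled out from these same values. Of the 74 genes, 36 were over 1 unit off on both arrays numbered 5, 27 of them lower. Against controls 1, 2 and 4 and against treated 1 to 4, MMP9 differed by −2.41 and −1.60, the inflammatory gene IL23A by −1.63 and −2.17, and ID1 by 1.73 and 1.69. A culture or batch shared by the arrays numbered 5 is a candidate explanation; the labels name none, and a technical and a biological origin of it were not tested apart.

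Other arrays stood out for single genes. AKR1B10 was at 2.64 on control 5, the highest control. ATF3 was lowest on both arrays numbered 5, at 4.29 on control 5 and 4.25 on treated 5. CDKN1A was lowest on treated 5, at 7.43. SQSTM1 was lowest on control 3, at 8.58, and so was the mean of the amino acid and integrated stress response list, at 6.29. REDIC1 was at 2.08 on control 5, the lowest control. SRPX was at 1.65 on treated 4, the only treated array off the lowest level. SLCO2A1 was highest among treated arrays on treated 1, at 2.87.

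The arrays can be split into groups of 5 in 126 ways, of which 100 were refitted, the real one included. Chance in how these arrays were grouped is unlikely for the counts of genes, though 100 splits cannot resolve a share below 1 in 100. Of the 100 splits 1, the real one, gave 47 higher genes, 6 lower genes or 24 genes changed by 2-fold. The highest other value was 1 in each case. The splits treat each array as independent, so chance between cultures is not excluded where arrays share one. For the number of lists chance cannot be excluded, since 46 of 100 splits gave at least 4 lists and the highest other gave 9; 18 of those 45 others exchanged a single pair of arrays with the real split. Taken one by one, each of the 4 lists had a camera p that 1 of 100 splits reached, the real one. The 4 were picked because they passed in that split, so this ranking favours it. The smallest p over all 23 lists was not compared between splits. As −log10 of p the real and highest other values were 54.5 and 21.7 for NRF2 targets, 10.2 and 7.14 for glutathione, 5.66 and 4.82 for the amino acid list, and 15.4 and 11.3 for the proteasome.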

How the results depend on the processing

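No result that passed reversed under any alternative, and all 53 genes kept their direction wherever they were measured. Against 47 higher, 6 lower, 24 changed by 2-fold and 4 lists, the counts that moved by more than 1.5 times, besides those with an array left out and the list count with the replicate block, were these. Median scaling gave 25 higher genes, the authors' deposited values 23 and array weights 71 higher and 16 lower. Of the alternatives chosen after seeing the data, the deposited values with a floor at 0 gave 31 higher and 3 lower, adding back a background of 12 units gave 13 genes changed by 2-fold, and number 5 as a batch gave 16 lower genes and 7 lists. The arrays numbered 1 to 4 alone gave 3 lower genes, and leaving out control 3 and both arrays numbered 5 gave 8 lists. Camera with an estimated correlation gave 2 lists, NRF2 targets and glutathione. The cause was not tested in these cases. With 1 array left out, higher genes ranged from 26 to 42, lower from 1 to 8, 2-fold changes from 16 to 25 and lists from 4 to 7. The list count was 7 without control 3, and the higher count was 28, 26 and 29 without controls 1, 2 and 4 and 30, 26 and 28 without treated 1, 3 and 4. A filter of log10 above 0.2 on at least 5 arrays, also chosen after seeing the data, gave 52 higher, 6 lower, 25 changed by 2-fold and 6 lists.

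Apart from number 5, replicate numbers gave little sign of pairing the arrays: the deviations of same-numbered arrays correlated at −0.107, 0.138, 0.0899, −0.0641 and 0.175, and for numbers 2 and 5 alone was the same number the best partner. With the replicate block there were 40 higher and 5 lower genes, 25 changed by 2-fold, and 7 lists, with G1/S (adjusted p 0.00876), metallothioneins (0.0396) and lung markers (0.0472) gained in camera at the preset correlation; with an estimated one and no block they had 0.817, 0.527 and 0.135. Across alternatives, named genes kept their call 591 times, lost it 152 times and gained it 3 times (HMOX1, adjusted p 0.00374 to 0.619 in limma); lists kept theirs 647 times, lost it 2 times and gained it 37 times. Of the named genes, 9 passed in every alternative that measured them: AKR1C2, AKR1B10, AKR1C3, MAP2, GPX2, AKR1B15, SLC7A11, AFP and NQO1. Not run as planned were slide as a block, for which no slide information was used here, and the background, offset and detection p settings, which have the stand-ins above. Signal near background limits REDIC1, SRPX and CYP4F3. It also limits the folds of AKR1B10, GPX2 and KIAA0319, above background on 4 of 5 control arrays, and of AKR1B15, on 3.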

Other observations

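Several genes outside the lists rose in treated cells and were named after their values were seen. PANX2, a pannexin channel gene, rose 2.84-fold (log2 difference 1.51 ± 0.09, SE, n = 5 per group; limma adjusted p = 3.9e-06), with a smaller SE than any passing gene of a larger change. GLA, the lysosomal alpha-galactosidase, rose 2.88-fold (1.52 ± 0.24, limma adjusted p = 0.0196), and CYP4F11, of the same family as CYP4F3, 2.57-fold. ABCB6, a porphyrin transporter, rose 2.27-fold, SLC6A6, the taurine transporter, 1.99-fold, and LRP8, a lipoprotein receptor, 2.05-fold. FECH, the last enzyme of heme synthesis, rose 1.80-fold, and the aldehyde dehydrogenase ALDH3A2 1.97-fold. The cytokine gene CCL26 rose 1.70-fold. ELAPOR1 was above background on 0 control and 4 treated arrays and was at least 1.15-fold higher (limma adjusted p = 0.0111). The ferritin heavy chain pseudogene FTH1P3 rose 1.62-fold, and whether its probe also binds ferritin heavy chain transcripts was not tested.

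At the probe level, 18954 probes with no single gene symbol entered the test, and 8 were higher and 2 lower. The largest difference among them, 3.76 ± 0.19 (limma adjusted p = 6.89e-06), was for ILMN_1687757, which is unnamed here. ILMN_2347949 differed by 1.12 ± 0.08, and of the lower probes ILMN_1838655 by −0.50. The other lower probe, ILMN_1883308, was above background on 0 arrays of either group, so it has no usable fold.

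Lists that did not pass also differed between arrays of one group. Relative to the mean of all arrays, the G1/S and DNA replication genes were at 0.36 on control 5 and 0.27 on treated 5, and between −0.29 and 0.03 on the other arrays. HMOX1 differed by 1.00 between groups over the arrays numbered 1 to 4 and by 4.63 between the arrays numbered 5, and SRXN1, sulfiredoxin, by 0.96 and 2.88. Of the 27 NRF2 targets, 23 were higher on treated 5 than on any other treated array, and 9 were higher on control 5 than on any other control. NQO1 was among both, and differed by 1.34 and 1.03. Relative to the mean of all arrays, the mean of the NRF2 list was 1.17 on treated 5, against 0.47 to 0.59 on the other treated arrays. On control 5 it was only slightly the highest of the controls, at −0.58 against −0.74 to −0.60.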
